A study of Mus musculus with 149 samples.

How the data were processed

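Gene expression was measured in lungs of BALB/c mice on 149 Affymetrix arrays, 1 array per animal. The animals were naive or sensitized with ovalbumin (OVA) and were challenged with saline, with buffer alone, or with thymic stromal lymphopoietin (TSLP) at 150, 500 or 1500 ng. Lungs were taken 6 or 24 h after the challenge. The labels give the buffer as 0.1% MSA, an abbreviation they do not expand. Each array was placed in 1 of 20 groups by its labels. The groups hold 6 to 8 arrays (3 groups of 6, 5 of 7 and 12 of 8), while the design text gives 8 animals per combination; any further animals were not analysed here.

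RNA was extracted with the mirVana kit, had RNA integrity numbers above 6, and was labelled from 100 ng with the 3'IVT Express kit, per the labels' protocols. The deposited values are log2 expression values made by RMA, per the submitters' processing notes. RMA corrects the background, normalizes between arrays and summarizes the probes of each probe set. The version of RMA and any filter on probe sets are not given in the sources used here. The table holds 26166 probe sets by 149 arrays, with values from 2.955 to 15.11 and array medians from 8.968 to 9.164. RMA values carry no counts or detection calls, so the precision stated here rests on the number of arrays and the spread between them. No pair of arrays held identical values.

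Probe sets were named through a table of the platform's annotation. Of the 26166 probe sets, 22892 named 1 gene, 260 named several genes and 3014 were not listed and stayed unnamed. For 22834 of the named probe sets the gene identifier was found in a RefSeq gene table, and no symbol needed an update. Genes were represented by the probe set with the highest mean over all arrays, among probe sets that name 1 gene, which left 13494 genes, 5715 of them with more than 1 probe set.

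The fit was made with limma 3.58.1 in R 4.3.3. It held 1 mean per group over all 149 arrays and eBayes with a constant prior (residual df 129, prior df 2.875, prior SD 0.1384; the median residual SD was 0.16). Each of 28 comparisons was tested on both sides with Benjamini-Hochberg adjustment over the 13494 genes at 0.05. TSLP doses were compared with buffer at the same sensitization and time, buffer with saline, OVA buffer with naive buffer, and 24 h with 6 h in saline groups. The difference between the 1500 ng effects in OVA and naive mice, and between 24 h and 6 h, was tested in the same fit. The dose slope is a linear contrast of the 3 TSLP group means on log10 dose, in log2 units per 10-fold dose, without buffer. Standard errors and adjusted p values in the text come from this limma fit unless another test is named. A number of arrays beside a change counts the arrays of the challenged group on that side of the mean of the comparison group.

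Lists of 32 immune pathways and cell type markers, including markers of tissues that lie beside the lung, were fixed with the groups, tests, alternatives and rules for naming genes before the data were examined. Of these, 31 had at least 4 measured members and were tested with camera at a preset correlation of 0.01, adjusted over the 31 lists per comparison. Camera with an estimated correlation and fry were alternatives. The genes named for 1500 ng TSLP against buffer were the 10 with the largest rise and the 6 with the largest fall past the threshold, and for the other comparisons 5 and 4. Added to them were up to 4 members with the smallest p of each list described, and 16 genes of type 2 airway inflammation, 14 of which were measured. Retnla and Arg1 were not analysed here because no probe set was named for them. Predicted and unnamed genes were skipped in these ranks. Where a gene was named outside these rules, the text says that it was chosen after its values were seen.

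The arrays carry beta-actin probe sets for the 3' and 5' ends of the transcript. Their log2 difference, which rises when RNA is degraded or poorly labelled at its 5' end, was computed for each array and compared between groups by exact permutation tests, 9 comparisons with Benjamini-Hochberg adjustment. Arrays with squamous gullet keratins were those with Krt4 and Krt13 more than 2 log2 units above their medians. The code was tested on simulated values with the real group sizes. Each gene had its overall mean and residual SD, with normal noise independent between genes. For 1500 ng TSLP against buffer in OVA mice at 24 h, 48%, 82%, 96% and 100% of 50 genes changed by 0.25, 0.5, 1 and 2 log2 units were recovered, with 11 false calls (0.0827%) among the unchanged genes.

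Alternatives were the mean of all probe sets per gene, every probe set on its own, a filter leaving out the dimmest 40% of genes, quantile normalization of the deposited values, array weights, a trended robust prior, the animal number as a replicate block, a fit on the compared groups alone, saline as the reference, a threshold of 0.01 for the overlaps, and leaving out each array in turn for the 1500 ng comparisons. After the data were seen, 7 settings were added: without the arrays with gullet keratins, with the beta-actin difference as a covariate, with both, and with a clock score as a covariate (the mean of Dbp, Per2, Per3, Tef and Nr1d1 minus the mean of Arntl, Npas2 and Clock) without the gullet arrays and either without or with the beta-actin covariate; without replicate 8 of naive 500 ng at 6 h, for the 500 ng comparison and the dose slope; and with saline as the reference of the differences between 1500 ng effects. The place of each array between naive and OVA mice, also chosen after the data were seen, is the median over 64 genes of its distance from the naive buffer mean, in percent of the distance to the OVA buffer mean at the same time. These genes were called the same way, with changes over 2-fold, in OVA against naive buffer at both times. The beta-actin difference itself moved with the groups, so a fit with this covariate also removes any effect of the challenge that goes along with it. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.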

Results

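Whole-lung expression was measured in BALB/c mice, 1 Affymetrix array per animal, to ask how a TSLP challenge affects airway inflammation in naive and OVA-sensitized animals. TSLP is an epithelial cytokine that acts through a receptor made of Crlf2 and Il7r. The 20 groups combined naive or OVA-sensitized mice with saline, buffer, or 150, 500 or 1500 ng TSLP, at 6 or 24 h, with 6 to 8 arrays each. The number of arrays limits the precision of every value.

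The beta-actin 3' minus 5' difference, a measure of RNA quality and labelling, differed between groups by exact permutation tests. At 6 h it was 2.57 ± 0.26 (SD, n = 8) in OVA buffer mice and 1.26 ± 0.12 (SD, n = 8) after 1500 ng TSLP, a difference of -1.31 (SE 0.10, adjusted p = 0.000465). In naive mice at 6 h the same difference was -0.53 (SE 0.16, adjusted p = 0.0132). At 24 h it ran the other way, by 0.32 (SE 0.14, adjusted p = 0.0274) in naive and 0.32 (SE 0.09, adjusted p = 0.000465) in OVA mice. Saline groups differed by time alone, by -1.04 (SE 0.20, adjusted p = 0.0007) in naive and -1.18 (SE 0.10, adjusted p = 0.000465) in OVA mice for 24 h minus 6 h. OVA buffer lay above naive buffer by 0.44 (SE 0.15, adjusted p = 0.015) at 6 h and by 0.03 (SE 0.07, adjusted p = 0.607) at 24 h. Naive buffer minus naive saline at 6 h was -0.28 (SE 0.22, adjusted p = 0.308). Another 6 arrays carried keratins of squamous gullet epithelium, with Krt13 at 10.4 or more against 6.06 or less in the other 143 arrays. They were naive buffer 6 h replicates 4 and 6, OVA buffer 6 h replicate 7, naive 150 ng 6 h replicate 5, OVA 1500 ng 6 h replicate 7 and naive buffer 24 h replicate 8.

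**Figure D1:**
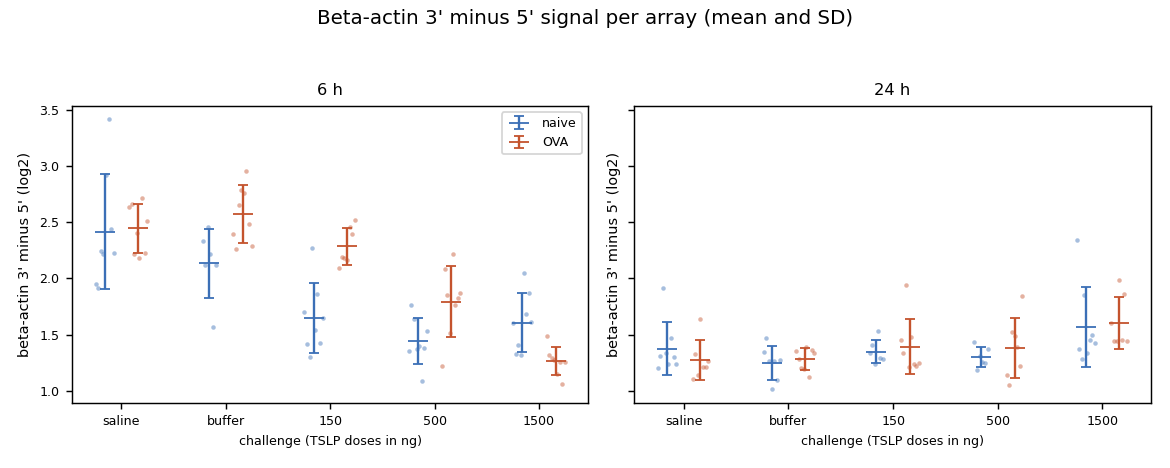
Beta-actin 3' minus 5' log2 signal of each array (points) by challenge, with the group mean and SD (bars), for naive and OVA-sensitized mice at 6 h (left) and 24 h (right). In OVA mice at 6 h the mean goes from 2.57 with buffer to 1.26 with 1500 ng TSLP, while all 24 h group means lie between 1.25 and 1.60.

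Sensitization was examined by comparing OVA with naive mice that both received buffer. Goblet cell and mucus genes were far higher in OVA lungs at both times. All 13 measured members rose at 6 h and 12 of 13 at 24 h, the same numbers when adjusted over the list alone. Camera gave this list adjusted p = 5.05e-17, or 0.0429 with an estimated correlation, at 6 h and 7.73e-28, or 0.000796, at 24 h. Clca1, a secreted goblet cell protein, was higher by 8.49 (SE 0.67, adjusted p = 2.7e-20, 8 of 8 arrays) at 6 h and 8.57 (SE 0.65, adjusted p = 3.02e-22, 8 of 8 arrays) at 24 h. Fcgbp, which encodes a mucus protein, rose by 2.996 (SE 0.27) and 2.68 (SE 0.26). The gel-forming mucin Muc5ac rose by 3.24 (SE 0.36) at 6 h. Slc26a4, an anion exchanger, and Fxyd4 rose by 3.49 (SE 0.37) and 3.19 (SE 0.44) at 24 h. Retnlb and Capn9 rose by 3.59 (SE 0.53) and 4.05 (SE 0.38) at 6 h. Gcnt3, a mucin glycosylation enzyme, rose by 3.28 (SE 0.35) at 24 h.

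Genes of alternatively activated macrophages rose in the same comparison, 6 of 9 at 6 h (8 adjusted over the list alone) and 7 of 9 at 24 h (7 adjusted over the list alone). The list had adjusted p = 4.6e-07, or 0.0524 with an estimated correlation, at 6 h and 1.02e-13, or 0.000796, at 24 h. The chitinase-like genes Chil4 and Chil3 were higher by 6.33 (SE 0.56) and 1.54 (SE 0.13) at 6 h. The macrophage elastase Mmp12 was higher by 1.88 (SE 0.44) at 6 h and 2.499 (SE 0.43) at 24 h. Antibody genes were higher too: the IgM heavy chain Ighm by 3.68 (SE 0.36) at 6 h and 4.78 (SE 0.34) at 24 h. The joining chain Jchain was higher by 1.51 (SE 0.29) and 2.19 (SE 0.28). Plasma cell markers rose for 5 of 11 and fell for 1 at 6 h (6 and 2 adjusted over the list alone), with adjusted p = 0.0292, or 0.668. The member that fell was Sdc1, a proteoglycan that epithelium also expresses, at -0.31 (SE 0.07). At 24 h 6 of 11 rose (9 rose and 1 fell adjusted over the list alone), with adjusted p = 3.34e-10, or 0.00637.

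At 24 h 4 more immune lists held with an estimated correlation. Eosinophil and monocyte chemokines rose for 4 of 9 (7 adjusted over the list alone), dendritic cell markers for 7 of 10 (8 adjusted over the list alone), and monocyte and interstitial macrophage markers for 4 of 10 (6 adjusted over the list alone). Each of these had adjusted p = 0.0168 with an estimated correlation. Dendritic cell chemokines and costimulation genes rose for 5 of 9 (6 adjusted over the list alone, adjusted p = 0.0403 with an estimated correlation). Ccl8 was higher by 2.96 (SE 0.29), the eosinophil chemokine Ccl11 by 2.28 (SE 0.32), Ccl17 by 1.88 (SE 0.32), and the complement gene C1qb by 0.52 (SE 0.07). The type 2 cytokine Il13 was higher by 1.31 (SE 0.31, adjusted p = 0.00307, 8 of 8 arrays). Cell division genes rose for 12 of 14 at 6 h and 10 of 14 at 24 h (13 at both times adjusted over the list alone). With an estimated correlation they had adjusted p = 0.583 at 6 h and 0.091 at 24 h. The kinase Cdk1 rose by 1.22 (SE 0.23) and 1.01 (SE 0.22). NK and cytotoxic cell markers fell for 5 of 10 at 6 h (7 adjusted over the list alone), including Gzma by -0.70 (SE 0.15), with adjusted p = 0.668 with an estimated correlation. Endothelial markers fell for 9 of 11 at 6 h (9 adjusted over the list alone), including Tek by -0.34 (SE 0.07), with adjusted p = 0.583 with an estimated correlation, beside the beta-actin difference of 0.44. The fat gene Adipoq was at -1.94 (SE 0.77) and Car3 at -1.83 (SE 0.73) at 6 h, and the muscle genes Myl3 and Tcap at -1.69 (SE 0.57) and -1.53 (SE 0.48). The naive buffer group held 2 of the gullet arrays. Without the gullet arrays only Tcap passed (-1.36, adjusted p = 0.0354), and against saline none of the 4 did. In all, 2113 genes rose and 2423 fell at 6 h, and 679 rose and 477 fell at 24 h. Quantile normalization moved the share of rises at 6 h from 46.6% to 59%, and a fit on these groups alone called 2338 genes at 6 h. At 24 h the count of 1156 became 4094 between saline groups and 2328 with array weights, and, without the gullet arrays, 415 with the clock score and 481 with both covariates.

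**Figure D2:**
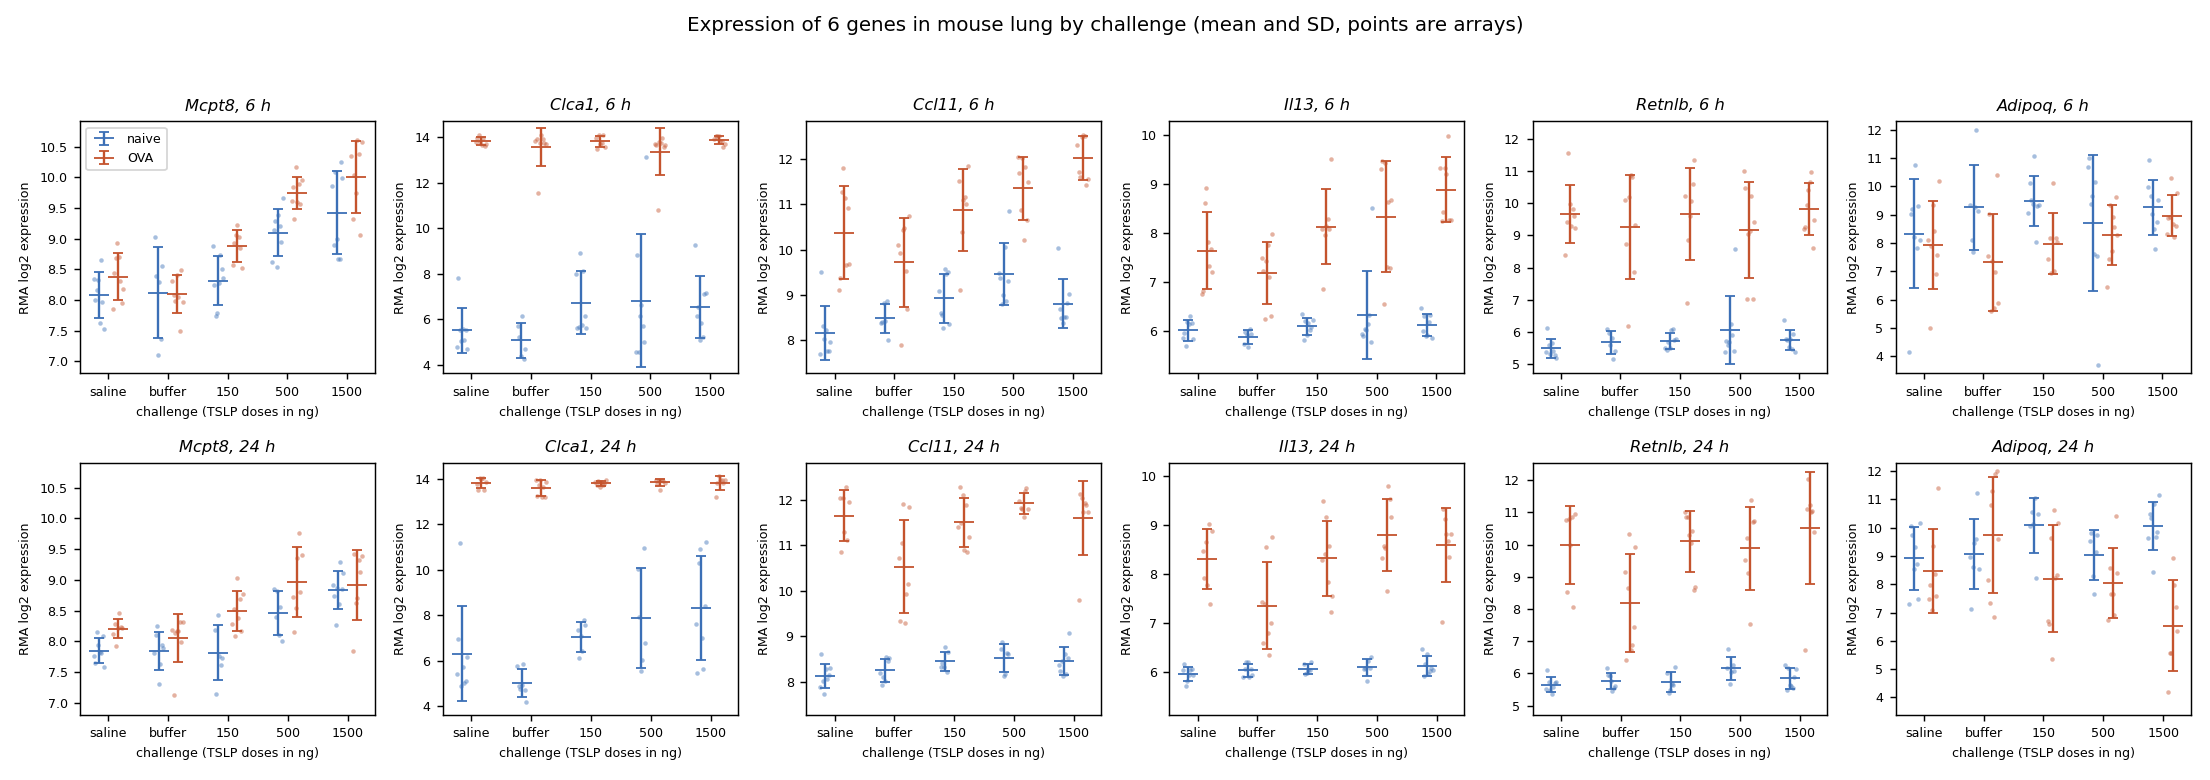
RMA log2 expression of Mcpt8, Clca1, Ccl11, Il13, Retnlb and Adipoq in each array (points) by challenge, with the group mean and SD (bars), for naive and OVA-sensitized mice at 6 h (top) and 24 h (bottom). Group means of Mcpt8 with 500 and 1500 ng lie above buffer in both kinds of mice at both times, though the 500 ng change in naive mice at 24 h (0.61, adjusted p = 0.95) did not pass, and group means of Clca1 lie from 13.37 to 13.88 in OVA and from 5.02 to 8.31 in naive mice, with 1 naive array at 13.15.

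In naive mice at 6 h, 1500 ng TSLP raised the basophil protease Mcpt8 by 1.302 (SE 0.23, adjusted p = 6.31e-05, 8 of 8 arrays) over buffer. Cd200r3, a receptor of basophils and mast cells, rose by 0.81 (SE 0.23, adjusted p = 0.00948, 7 of 8 arrays). Cyp11a1, the enzyme that starts steroid synthesis from cholesterol, rose by 0.84 (SE 0.18, adjusted p = 0.00092, 7 of 8 arrays). The glucocorticoid-responsive Zbtb16 rose by 1.15 (SE 0.36, adjusted p = 0.0216, 7 of 8 arrays). None of the 14 genes of type 2 inflammation passed against buffer. Il13 changed by 0.24 (SE 0.33, adjusted p = 0.657), Il4 by 0.25 (SE 0.19, adjusted p = 0.387), and Il5 by -0.05 (SE 0.28, adjusted p = 0.926). The SE of Il13 pools all groups, while its SDs here were 0.145 (buffer) and 0.23 (1500 ng), so smaller changes may be missed. Ccl11 changed by 0.33 (SE 0.34, adjusted p = 0.542), Ccl17 by 0.26 (SE 0.33, adjusted p = 0.628) and Clca1 by 1.47 (SE 0.67, adjusted p = 0.117). Against saline in place of buffer Ccl17 passed (0.90, adjusted p = 0.0121), Ccl11 was at 0.65 (adjusted p = 0.0849) and the other 12 did not pass. The other large rises were Elf4 (0.85, SE 0.27), Reep3 (0.81, SE 0.16), Zfp40 (0.75, SE 0.24), Bak1 (0.64, SE 0.13), Ptprj (0.64, SE 0.22) and Mapk1ip1l (0.64, SE 0.23), beside the beta-actin difference of -0.53. Mcpt8 with the beta-actin covariate was at 1.35 (adjusted p = 0.000174), Cyp11a1 at 0.86 (adjusted p = 0.00303) and Cd200r3 at 0.80 (adjusted p = 0.0344). Elf4 was then at 0.09 (adjusted p = 0.84) and Bak1 at 0.26 (adjusted p = 0.0829).

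The largest falls were squamous epithelium and skeletal muscle genes, Lce3f by -2.89 (SE 0.94), Myh8 by -2.54 (SE 0.79), Tnnc2 by -2.48 (SE 0.85), Krtdap by -2.23 (SE 0.82), Mt4 by -2.21 (SE 0.73) and Rptn by -2.05 (SE 0.70). The naive buffer 6 h group held 2 of the arrays with gullet keratins, and without those arrays none of these genes passed. Lce3f, Myh8, Tnnc2, Krtdap, Mt4 and Rptn were then at -0.27, -0.05, -0.16, -0.05, -0.17 and -0.34. Mcpt8 was then at 0.86 (adjusted p = 0.0053), Cyp11a1 at 0.58 (adjusted p = 0.0231) and Cd200r3 at 0.47 (adjusted p = 0.153). Clock genes rose for 2 of 14 (2 adjusted over the list alone), Cry1 by 0.47 (SE 0.10) and Nr1d2 by 0.40 (SE 0.11). Alveolar type 1 markers rose for 2 of 10 (5 adjusted over the list alone), Akap5 by 0.26 (SE 0.06) and Cav1 by 0.16 (SE 0.06). Club cell markers rose for 1 of 9 (0 adjusted over the list alone), Aldh1a1 by 0.11 (SE 0.04), and endothelial markers for 1 of 11 (1 adjusted over the list alone), Calcrl by 0.33 (SE 0.07). Camera called these 4 lists with adjusted p from 0.0172 to 0.0305, and each had adjusted p = 0.951 with an estimated correlation. Akap5 and Aldh1a1 did not pass against saline. In all, 746 genes rose and 1325 fell. The count was 629 with the beta-actin covariate, 3483 without the gullet arrays, 5774 against saline, 20 in a fit on these groups alone, and 807, 1178 and 3413 without naive buffer 6 h replicates 5, 2 and 6.

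In OVA mice at 6 h, 1500 ng TSLP raised the retinoic acid synthesis gene Aldh1a3 by 3.35 (SE 0.43, adjusted p = 4.04e-11), Ccl11 by 2.29 (SE 0.31, adjusted p = 3.07e-10), Mcpt8 by 1.91 (SE 0.21, adjusted p = 7.38e-14), each in 8 of 8 arrays. The matrix-binding Tnfaip6 rose by 1.84 (SE 0.22, adjusted p = 2.02e-12, 8 of 8 arrays). The type 2 cytokines Il13, Il5 and Il4 rose by 1.69 (SE 0.30, adjusted p = 7.22e-07), 1.18 (SE 0.26, adjusted p = 3.67e-05) and 0.82 (SE 0.18, adjusted p = 3.28e-05). The epithelial alarmin Il33 rose by 0.76 (SE 0.12, adjusted p = 3.95e-08), and all of these changes held in 8 of 8 arrays. The chemokines Ccl17 and Ccl24 rose by 0.93 (SE 0.31, adjusted p = 0.00572) and 0.99 (SE 0.36, adjusted p = 0.0145), while Tslp itself was lower by -0.39 (SE 0.12, adjusted p = 0.00195). Against saline Il13 was at 1.24, Il5 at 0.66 and Il4 at 0.40 (adjusted p = 0.0438), while Ccl17 (0.59, adjusted p = 0.0841) and Ccl24 (0.16, adjusted p = 0.717) did not pass. Of the other genes of type 2 inflammation, Clca1 (0.31, SE 0.62), Muc5ac (0.05, SE 0.33), Chil3 (0.17, SE 0.12), Prg2 (0.52, SE 0.30), S100a8 (0.20, SE 0.14), Il7r (0.24, SE 0.14) and Crlf2 (-0.12, SE 0.06) did not pass.

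The list of type 2 cytokines and receptors had 8 of 10 members up and 2 down, the same adjusted over the list alone. Stat6, the transcription factor of Il4 and Il13 signalling, fell by 0.38 (SE 0.05), and Il13ra1 rose by 0.47 (SE 0.09). Eosinophil and monocyte chemokines rose for 6 of 9 (6 adjusted over the list alone), with Ccl12 up by 0.93 (SE 0.27) and Ccl8 by 0.77 (SE 0.28). Neutrophil chemokines and acute inflammation genes rose for 9 of 17 and fell for 1 (9 and 1 adjusted over the list alone). The cytokine Il1b rose by 1.11 (SE 0.21), its antagonist Il1rn by 1.47 (SE 0.28) and the endothelial selectin Selp by 0.87 (SE 0.20). Interferon response genes rose for 7 of 15 (7 adjusted over the list alone). The chemokines Cxcl9 and Cxcl10 rose by 1.72 (SE 0.40) and 1.61 (SE 0.33), Iigp1 by 1.17 (SE 0.18) and Ifit2 by 0.9968 (SE 0.12). Against saline Ccl8 (0.31, adjusted p = 0.337) and Cxcl9 (0.81, adjusted p = 0.0707) did not pass, and Cxcl10 was at 1.03 and Iigp1 at 0.52. Immediate early genes rose for 8 of 11 and fell for 1 (8 and 1 adjusted over the list alone), with Jun up by 0.46 (SE 0.06) and Junb by 0.55 (SE 0.10). Dendritic cell markers rose for 5 of 10 (5 adjusted over the list alone), with Cd209a up by 0.95 (SE 0.17) and the class II gene H2-Aa by 0.59 (SE 0.11). Endothelial markers rose for 10 of 11 and fell for 1 (10 and 1 adjusted over the list alone), with the VEGF receptors Kdr and Flt1 up by 0.73 (SE 0.11) and 0.73 (SE 0.12). Camera called these 7 lists, endothelial markers with adjusted p = 0.0105 and the others with adjusted p = 0.039, and each had adjusted p = 0.617 with an estimated correlation.

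The same 8 and 8 arrays differed by -1.31 in beta-actin 3' minus 5'. With that difference as a covariate, Aldh1a3 was at 2.70 (SE 0.58, adjusted p = 0.00245), Mcpt8 at 2.03 (SE 0.28, adjusted p = 6.95e-07), and Ccl11 at 1.65 (SE 0.42, adjusted p = 0.00864). Tnfaip6 was at 1.59 (SE 0.30, adjusted p = 0.00078), Il13 at 1.52 (SE 0.41, adjusted p = 0.0139), Il5 at 1.05 (SE 0.35, adjusted p = 0.045) and Il4 at 0.74 (SE 0.24, adjusted p = 0.0422). Il33 was at 0.52 (adjusted p = 0.0308), Cxcl9 at 2.07 (adjusted p = 0.0114), Ifit2 at 0.64 (adjusted p = 0.00644) and Iigp1 at 1.004 (adjusted p = 0.00563). Thbs1 (2.05, SE 0.25), Rbbp4 (2.05, SE 0.27), Pfn1 (2.004, SE 0.23), Elf4 (1.96, SE 0.25) and the chaperone Hyou1 (1.89, SE 0.23) were among the largest rises. None of them passed with the covariate, where they were at 0.64, 0.34, 0.42, 0.08 and 0.18. Kdr was then at 0.01 (adjusted p = 0.96), Flt1 at 0.03 (adjusted p = 0.921) and H2-Aa at 0.05 (adjusted p = 0.855). Tslp was then at -0.07 (adjusted p = 0.822), and the calls of Ccl17 (1.08, adjusted p = 0.082), Ccl24 (0.82, adjusted p = 0.295), Il1b (0.49, adjusted p = 0.26) and Il1rn (0.55, adjusted p = 0.349) were lost. An antibody light chain segment of the Igkv15 family rose by 1.86 (SE 0.54) and was at 0.74 (adjusted p = 0.545) with the covariate and 0.90 (adjusted p = 0.139) against saline. Among the largest falls, Rap1gap (-1.42, SE 0.12) and Sema4f (-1.40, SE 0.12) were at -0.66 (adjusted p = 0.00141) and -0.64 (adjusted p = 0.000965) with the covariate. The calls of Nppa (-1.89, SE 0.67), the telomerase gene Tert (-1.81, SE 0.26), Csdc2 (-1.53, SE 0.19) and Bcan (-1.42, SE 0.20) were lost. Nppa was at -0.69 (adjusted p = 0.372) against saline. The counts were 3350 genes up and 4844 down, of which 207 changed over 2-fold, and 358 up and 684 down with the covariate.

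In naive mice at 24 h, 1500 ng TSLP raised the goblet cell gene Clca1 by 3.29 (SE 0.65, adjusted p = 0.00174, 8 of 8 arrays) over buffer. Its SDs were 0.604 (buffer) and 2.29 (1500 ng), while the SE pools all groups. Basophil and mast cell genes rose: Mcpt8 by 0.98 (SE 0.22, adjusted p = 0.00608), the IgE receptor chain Fcer1a by 0.9974 (SE 0.21, adjusted p = 0.00334) and its partner Ms4a2 by 0.86 (SE 0.19, adjusted p = 0.00472), each in 8 of 8 arrays. Circadian clock genes changed as well. Per1, Per2 and Dbp rose by 1.05 (SE 0.21, adjusted p = 0.00275), 1.01 (SE 0.22, adjusted p = 0.00407) and 0.97 (SE 0.20, adjusted p = 0.00334). Npas2 and Arntl, which peak in the opposite phase, fell by 1.10 (SE 0.21, adjusted p = 0.00174) and 0.79 (SE 0.17, adjusted p = 0.00551), each in 8 of 8 arrays. Cyp26b1, which degrades retinoic acid, rose by 1.40 (SE 0.39, adjusted p = 0.0472), Akr1c18 by 1.13 (SE 0.31, adjusted p = 0.0416) and Sphk2 by 0.92 (SE 0.20, adjusted p = 0.00501). The other falls were Ahsa1 by 0.76 (SE 0.21), Fam124b by 0.71 (SE 0.20), Spon2 by 0.59 (SE 0.14) and Dnase1l2 by 0.57 (SE 0.12). Of the 14 genes of type 2 inflammation only Clca1 passed. Il13 was at 0.09 (SE 0.31, adjusted p = 0.92), Ccl11 at 0.19 (SE 0.32, adjusted p = 0.815) and Ccl17 at 0.74 (SE 0.32, adjusted p = 0.241).

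Mast cell and basophil markers rose for 3 of 11 (5 adjusted over the list alone), with adjusted p = 0.000187, or 0.282 with an estimated correlation. Mucus and goblet cell genes rose for 1 of 13 (4 adjusted over the list alone), with adjusted p = 0.00611, or 0.987. Bpifb1 (1.59, SE 0.48, adjusted p = 0.084) and Agr2 (1.45, SE 0.49, adjusted p = 0.119) did not pass. Clock genes rose for 6 of 14 and fell for 2 (7 and 3 adjusted over the list alone), with adjusted p = 0.00701, or 0.776. The beta-actin difference between these groups was 0.32. In all, 82 genes rose and 50 fell. Against saline Clca1 was at 2.004 (adjusted p = 0.0977), and Akr1c18, Ahsa1, Spon2 and Dnase1l2 did not pass. The count was 44 with the beta-actin covariate, 78 without the gullet arrays, 60 in a fit on these groups alone, 67, 54 and 87 without naive buffer 24 h replicates 8, 7 and 5, and 57, 59, 219 and 86 without naive 1500 ng 24 h replicates 1, 4, 5 and 7.

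In OVA mice at 24 h, genes of mucus-producing epithelium were higher with 1500 ng TSLP than with buffer. Retnlb rose by 2.32 (SE 0.51, adjusted p = 0.000148, 6 of 7 arrays), Fxyd4 by 2.08 (SE 0.44, adjusted p = 8.56e-05, 6 of 7 arrays), and Muc5ac by 1.18 (SE 0.34, adjusted p = 0.00366, 6 of 7 arrays). The goblet cell transcription factors Foxa3 and Spdef rose by 1.08 (SE 0.21, adjusted p = 1.99e-05) and 1.06 (SE 0.22, adjusted p = 6.24e-05). The airway epithelial transcription factor Sox9 rose by 1.60 (SE 0.32, adjusted p = 2.92e-05). Other large rises were Lemd1 (1.93, SE 0.43), Capn9 (1.91, SE 0.36), Corin (1.75, SE 0.37), Scin (1.59, SE 0.36), the lipoxygenase Alox15 (1.58, SE 0.47), Duoxa1 (1.57, SE 0.44) and Guca2a (1.48, SE 0.32). Il13 and Il5 rose by 1.24 (SE 0.31, adjusted p = 0.000925) and 1.08 (SE 0.27, adjusted p = 0.000739). Ccl24, Ccl17 and Ccl11 rose by 1.32 (SE 0.38, adjusted p = 0.00306), 1.20 (SE 0.32, adjusted p = 0.00137) and 1.08 (SE 0.32, adjusted p = 0.00525), and Crlf2 by 0.16 (SE 0.07, adjusted p = 0.0448). Clca1 (0.22, SE 0.65), Il4 (0.23, SE 0.19), Il7r (0.13, SE 0.15), Tslp (0.05, SE 0.12), Chil3 (0.08, SE 0.13), S100a8 (-0.16, SE 0.15) and Prg2 (0.46, SE 0.31) did not pass. Replicate 1 of the 1500 ng group was low in Ccl11, Retnlb and Clca1.

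The genes with the largest falls fell in 7 of 7 arrays each. Adipoq fell by 3.20 (SE 0.74, adjusted p = 0.000274), Car3 by 2.64 (SE 0.70, adjusted p = 0.00137), Tmem45b by 2.57 (SE 0.70, adjusted p = 0.00191), and Scara5 by 2.23 (SE 0.31, adjusted p = 1.58e-08). Cyp2e1 fell by 2.18 (SE 0.46, adjusted p = 7.02e-05) and Pck1 by 1.98 (SE 0.60, adjusted p = 0.00552). Adipoq, an adipocyte hormone, had an SD of 2.07 (n = 8) in the buffer group, with replicate 7 at 12 beside the muscle genes Acta1 (13.18) and Ckm (11.37). The list of fat, muscle, gullet and thymus markers had 1 of 8 members down (1 adjusted over the list alone) and was not called (adjusted p = 0.339). It pools tissues and cannot decide on fat alone. Alveolar macrophage markers fell for 7 of 14 (7 adjusted over the list alone), with adjusted p = 0.0303. Fabp1 was at -1.87 (SE 0.32), Cidec, also a lipid droplet gene of fat, at -1.97 (SE 0.36), Il18 at -1.02 (SE 0.22) and the cholesterol exporter Abcg1 at -0.62 (SE 0.12). Endothelial markers fell for 8 of 11 (8 adjusted over the list alone), with adjusted p = 0.0228. Flt1 was at -0.69 (SE 0.13) and Kdr at -0.47 (SE 0.11). Alveolar type 1 markers fell for 7 of 10 (7 fell and 1 rose adjusted over the list alone), with adjusted p = 0.0303. Akap5 was at -0.31 (SE 0.06) and Emp2 at -0.19 (SE 0.04). Mucus and goblet cell genes rose for 7 of 13 (8 adjusted over the list alone), with adjusted p = 0.0178. Dendritic cell chemokines and costimulation genes rose for 4 of 9 (4 adjusted over the list alone), with adjusted p = 0.0404. Each of these 5 lists had adjusted p = 0.779 with an estimated correlation. Ccl22, a chemokine that draws T helper type 2 cells, rose by 1.41 (SE 0.31), Cd86 by 0.57 (SE 0.12) and Cd40 by 0.48 (SE 0.09). All of this lies beside a beta-actin difference of 0.32. In all, 2829 genes rose and 2362 fell, of which 89 changed over 2-fold.

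The reference group mattered for these OVA 24 h values. Against saline in place of buffer, Retnlb was at 0.52 (adjusted p = 0.5), Fxyd4 at 0.62 (adjusted p = 0.319), Muc5ac at 0.25 (adjusted p = 0.639), and Il13 at 0.29 (adjusted p = 0.544). Il5 was at 0.26 (adjusted p = 0.529), Ccl17 at 0.21 (adjusted p = 0.679), Ccl11 at -0.05 (adjusted p = 0.929) and Prg2 at -1.04 (adjusted p = 0.00929). Adipoq (-1.93, adjusted p = 0.0457), Scara5 (-1.76, adjusted p = 9.86e-06), Fabp1 (-0.81, adjusted p = 0.0489), Flt1 (-0.46, adjusted p = 0.00378), Kdr, Abcg1, Emp2 and Cd40 passed against either reference, and the other genes named as risen or fallen did not. The counts against saline were 3934 at 1500 ng, 42 at 500 ng and 2 at 150 ng.

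Lower doses were compared with buffer in the same way. In naive mice at 6 h, 1483 genes rose and 2191 fell with 150 ng and 2134 rose and 3541 fell with 500 ng. Among OVA mice at 6 h, 18 rose and 4 fell with 150 ng and 2558 rose and 2971 fell with 500 ng. Naive mice at 24 h had 12 up and 17 down with 150 ng. With 500 ng limma called 0 genes, with 637 genes at an unadjusted p under 0.05, while array weights gave 3 and saline as the reference 2. Among OVA mice at 24 h, 972 rose and 440 fell with 150 ng and 1002 rose and 587 fell with 500 ng. With the beta-actin covariate the 6 h counts were 1639 and 2077 in naive mice and 14 and 1078 in OVA mice for 150 and 500 ng. In a fit on the compared groups alone, 150 ng gave 1177 genes in naive and 0 in OVA mice at 6 h (limma, 1077 at an unadjusted p under 0.05) and 104 in naive and 16 in OVA mice at 24 h, and 500 ng gave 358 in OVA mice at 24 h. Replicate 8 of naive 500 ng at 6 h had values near those of OVA mice.

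Mcpt8 followed dose in the linear contrast over the 3 TSLP doses in naive mice at both times. It rose by 1.11 (SE 0.21, adjusted p = 0.00618) per 10-fold dose at 6 h and by 1.02 (SE 0.23, adjusted p = 0.0127) at 24 h. Its slopes in OVA mice, chosen after their values were seen, were 1.14 (SE 0.22, adjusted p = 5.21e-06) at 6 h and 0.43 (SE 0.22, adjusted p = 0.163) at 24 h. Other positive slopes in naive mice were Hydin (0.56, SE 0.14), Slc22a12 (0.36, SE 0.07), Esco1 (0.33, SE 0.08) and Adsl (0.30, SE 0.07) at 6 h. At 24 h the others were Per1 (0.85, SE 0.22), Ms4a2 (0.75, SE 0.20), Cyp11a1 (0.70, SE 0.18) and Stbd1 (0.70, SE 0.14). Negative slopes were seen for Zc4h2 (-0.47), Pfdn2 (-0.40), Ptpre (-0.40) and Gyg (-0.38) at 6 h and for Egr1 (-0.71), Nsun3 (-0.62), Cwc25 (-0.56) and Etv6 (-0.50) at 24 h. The slope in OVA mice at 6 h was positive for Cxcl9 (1.36, SE 0.42, adjusted p = 0.00419), Rbbp4 (1.74), Pfn1 (1.60), Elf4 (1.51) and Mapk1ip1l (1.38). It was negative for Tert (-2.03), Ncam2 (-1.52), Snord104 (-1.31) and Rpp25 (-1.17), beside a beta-actin slope of -1.02 per 10-fold dose. The slopes of Cxcl9 (1.62, adjusted p = 0.0324), Ncam2 (-1.20, adjusted p = 0.00273), Tert (-1.07, adjusted p = 0.0144) and Rpp25 (-0.98, adjusted p = 0.0141) passed with the beta-actin covariate and those of Rbbp4, Pfn1, Elf4, Mapk1ip1l and Snord104 did not. At 24 h in OVA mice Cxcl9 had a slope of -1.24 (SE 0.42, adjusted p = 0.0304), an Igkv15 family segment of -1.95 (SE 0.55), the glycine receptor gene Glrb of -1.20 (SE 0.27) and Scara5 of -1.08 (SE 0.31). Fbxw13 (1.05), Per2 (0.86, SE 0.22), Adamts20 (0.78), Pde2a (0.76) and Nat8f3 (0.75) had positive slopes. The slope passed for 23 genes (10 up, 13 down) at 6 h and 61 (34 up, 27 down) at 24 h in naive mice. In OVA mice it passed for 6801 (2815 up, 3986 down) at 6 h and 2029 (946 up, 1083 down) at 24 h, where quantile normalization moved the share of positive slopes from 46.6% to 56.4%. With the beta-actin covariate 957 of these slopes were called in OVA mice at 6 h, and 44 and 40 in naive mice at 6 and 24 h. In a fit on the compared groups alone the naive slopes passed for 0 genes at 6 h (limma, 2040 at an unadjusted p under 0.05), which ends the call of Mcpt8 there, and for 19 at 24 h.

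The effect of 1500 ng TSLP differed between OVA and naive mice. At 6 h it was larger in OVA mice for Aldh1a3 by 3.02 (SE 0.64, adjusted p = 0.000146). It was also larger for the interferon-inducible chemokines Cxcl9, Cxcl11 and Cxcl10 by 2.33 (SE 0.59, adjusted p = 0.00155), 2.03 (SE 0.51, adjusted p = 0.00123) and 1.75 (SE 0.49, adjusted p = 0.00418), and for the T cell costimulatory receptor Cd28 by 1.10 (SE 0.31, adjusted p = 0.00373). After the beta-actin covariate these were 2.64, 2.54, 1.91, 1.58 and 1.01, each past the threshold. T cell markers had 6 of 15 members up in this difference (6 adjusted over the list alone) and interferon response genes 5 of 15 (5 adjusted over the list alone), both with adjusted p = 0.0161, or 0.628 with an estimated correlation. Club cell markers had 5 of 9 down (5 adjusted over the list alone), with the same adjusted p values, including Cbr2 by -0.23 (SE 0.04) and Cyp2f2 by -0.29 (SE 0.07). Light chain segments of the Igkv15 (2.20, SE 0.79) and Igkv14 (2.15, SE 0.64) families were also higher. Tert (-1.41), Sema4f (-1.41), Depp1 (-1.35) and Acr (-1.32) were lower, beside a beta-actin value of -0.79 for the same contrast. In all, 1886 genes were higher and 2405 lower in this difference at 6 h, and the total was 967 with the beta-actin covariate and 2745 without the gullet arrays. With saline in place of buffer as the reference of both effects 983 genes passed. Aldh1a3 (2.01, adjusted p = 0.0325), Sema4f (-0.86), Depp1 (-0.87) and Acr (-0.68) did, while Cxcl9 (1.4, adjusted p = 0.101), Cxcl11 (0.82, adjusted p = 0.278), Cxcl10 (0.59, adjusted p = 0.449) and Cd28 (0.71, adjusted p = 0.108) did not. Nor did the Igkv15 (0.50, adjusted p = 0.718) and Igkv14 (0.55, adjusted p = 0.615) family segments, Tert (-0.98, adjusted p = 0.0773), Cbr2 (-0.12, adjusted p = 0.0578) and Cyp2f2 (-0.12, adjusted p = 0.21), nor the T cell genes Cd3g, Cd247 and Cd8b1.

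At 24 h the difference was positive for Lemd1 (2.04, SE 0.61), Mug1 (1.97, SE 0.57), Capn9 (1.94, SE 0.51), Egln3 (1.56, SE 0.46), Guca2a (1.53, SE 0.45) and the type 2 transcription factor Gata3 (0.61, SE 0.17, adjusted p = 0.0191). It was negative for Adipoq (-4.19, SE 1.05, adjusted p = 0.0117), Tmem45b (-3.73, SE 0.99), Car3 (-3.47, SE 0.98) and Clca1 (-3.07, SE 0.91, adjusted p = 0.0341). Clca1 was already at 13.59 in OVA buffer mice, against 5.02 in naive buffer mice, and stayed near that level in every OVA group, so its difference cannot be read as a weaker response. Alveolar macrophage markers were lower for 4 of 14 (6 adjusted over the list alone), including Cidec (-2.29, SE 0.52), Fabp4 (-2.14, SE 0.62) and Fabp1 (-1.81, SE 0.45), with adjusted p = 0.00581, or 0.66 with an estimated correlation. Type 2 cytokines and receptors were higher for 2 of 10 (6 adjusted over the list alone), with adjusted p = 0.0239, or 0.683. In all, 259 genes were higher and 337 lower. With saline as the reference of both effects 116 genes passed and none of the genes named here did. Gata3 was then at -0.0259 (adjusted p = 0.964), Capn9 at 0.83 (adjusted p = 0.447) and Adipoq at -3.06 (adjusted p = 0.125).

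Genes called with 1500 ng in both kinds of mice, which share no control arrays, numbered 1508 in the same direction at 6 h (463 up, 1045 down) and 86 in opposite directions, against 660.8 in the same direction for independent lists. At 24 h 96 were shared (58 up, 38 down) and 0 were called in opposite directions by limma, against 25.94 for independent lists. With the beta-actin covariate 43 were shared at 6 h, with 15 in opposite directions, and 31 at 24 h, against 23.86 and 7.264.

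The 1500 ng effect also differed between times. In OVA mice 24 h minus 6 h was positive for Tert (2.67, SE 0.37), Lemd1 (2.36, SE 0.60), Erich6 (2.13, SE 0.27), Rasgrf1 (2.10, SE 0.24) and Dbp (2.10, SE 0.28). It was negative for Adipoq (-4.85, SE 1.03), Car3 (-4.11, SE 0.97), Tmem45b (-3.66, SE 0.97) and Scara5 (-2.95, SE 0.43). Endothelial markers had 9 of 11 down and 1 up (9 and 1 adjusted over the list alone), with adjusted p = 0.00328, and alveolar type 1 markers 7 of 10 down (7 adjusted over the list alone), with adjusted p = 0.0481, or 0.93 for each with an estimated correlation. In naive mice the difference was positive for Fcna (1.68, SE 0.61), Thrsp (1.21, SE 0.40), Akr1c18 (1.21, SE 0.44), Ephx2 (1.08, SE 0.39) and Erich6 (1.06, SE 0.28). It was negative for Zbtb16 (-1.61, SE 0.50), Elf4 (-1.36, SE 0.38), Rbbp4 (-1.26, SE 0.41) and Zfp40 (-1.24, SE 0.34). Counts were 4677 up and 3440 down in OVA and 1542 up and 764 down in naive mice, beside beta-actin values of 1.64 and 0.85 for these contrasts. They came to 3155 and 170 with the beta-actin covariate, and in naive mice to 4754 with saline as the reference of both effects and 1111 in a fit on the compared groups alone. With saline as the reference Fcna (0.62, adjusted p = 0.419) in naive and Tmem45b (-2.07, adjusted p = 0.0631) in OVA mice did not pass.

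Buffer was set against saline to measure the carrier alone. In OVA mice at 24 h eosinophil genes were lower with buffer. The chemokine receptor Ccr3 was at -1.56 (SE 0.30, adjusted p = 0.0114, 8 of 8 arrays), the peroxidase Epx at -1.56 (SE 0.33, adjusted p = 0.0144, 7 of 8 arrays) and the major basic protein Prg2 at -1.496 (SE 0.31, adjusted p = 0.0144, 8 of 8 arrays). Eosinophil markers fell for 3 of 4 (3 adjusted over the list alone), with adjusted p = 5.02e-08, or 0.0133 with an estimated correlation. T cell markers fell for 7 of 15 (11 adjusted over the list alone), including Icos by -0.88 (SE 0.21), Cd3g by -0.68 (SE 0.17) and Cd4 by -0.63 (SE 0.15). This list had adjusted p = 4.28e-16, or 0.0553. Dendritic cell chemokines and costimulation genes fell for 2 of 9 (6 adjusted over the list alone), Ccl22 by -1.24 (SE 0.31) and Ccr7 by -0.52 (SE 0.14). It had adjusted p = 1.68e-06, or 0.0553. Pdcd1lg2, an inhibitory ligand, fell by 1.3 (SE 0.32), Igkv6-20 by 1.44 (SE 0.38), and Gata3 by 0.54 (SE 0.12). Pon1 (1.09, SE 0.30), Lipf (1.01, SE 0.25), Il18 (0.84, SE 0.22), Fpr2 (0.83, SE 0.21) and Igfbp3 (0.72, SE 0.19) rose. In all, 33 genes rose and 86 fell. A fit on these groups alone ended all of these gene calls, with 0 genes by limma and 1784 at an unadjusted p under 0.05, while array weights gave 2303.

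With buffer in OVA mice at 6 h 17 genes rose and 31 fell, with a split of 35.4% rises as deposited and 51.6% after quantile normalization. They included the basophil surface enzyme Enpp3 by -0.64 (SE 0.16), Gzmb by -0.67 (SE 0.16) and Tm4sf5 by -0.62 (SE 0.14), and Pak6 by 0.55 (SE 0.13). Naive mice at 6 h had 1092 genes up and 922 down, 54.2% rises as deposited and 43.4% after quantile normalization. A fit on the compared groups alone gave 0 genes by limma in OVA and in naive mice at 6 h, with 1305 and 2268 at an unadjusted p under 0.05, and array weights gave 2 and 365. The largest rises there were Lce3f (2.87), Myh8 (2.49), Cxcl3 (2.39, SE 0.77), Krtdap (2.38) and Mt4 (2.11). Without the gullet arrays Lce3f, Myh8, Cxcl3, Krtdap and Mt4 were at 0.26, 0.01, 2.32, 0.20 and 0.07. The largest falls were Ptchd1 (-1.14, SE 0.21), Hoxa4 (-0.88, SE 0.13), Fermt3 (-0.76, SE 0.13) and Pde2a (-0.75, SE 0.17). Neutrophil chemokines and acute inflammation genes rose for 9 of 17 (9 adjusted over the list alone), including Cxcl1 by 1.38 (SE 0.42). The list had adjusted p = 0.00025, or 0.998 with an estimated correlation. Without the gullet arrays Cxcl1 was at 1.25 (adjusted p = 0.0874). Limma called 1 gene in naive mice at 24 h, Dusp28 (0.45, SE 0.09, adjusted p = 0.0204), with 452 at an unadjusted p under 0.05, and 0 in a fit on these groups alone, with 584.

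Time itself was compared in saline groups. In naive mice Npas2 was higher at 24 h than at 6 h by 2.26 (SE 0.21) and Dbp lower by -1.53 (SE 0.20). In OVA mice Dbp was lower by -1.65 (SE 0.20), Cxcl5 higher by 2.59 (SE 0.51), Ccr3 higher by 2.27 (SE 0.30) and Igkv6-20 higher by 2.10 (SE 0.38). Elf4 (2.08 and 2.19), Pfn1 (1.99 and 2.12) and, in naive mice, H2ac19 (1.95) and Zfp40 (1.94) rose. Elf4 with the beta-actin covariate was at 0.59 and 0.51 and Pfn1 at 0.73 and 0.70. Sphk2 (-1.59 and -1.61), Rasd2 (-1.59) and Nr5a2 (-1.33) in naive mice, and Rpp25 (-1.73) and Tert (-1.61) in OVA mice, were among the largest falls. Endothelial markers rose for 10 of 11 and fell for 1 in naive mice (10 and 1 adjusted over the list alone), with adjusted p = 0.0175, or 0.992 with an estimated correlation. In OVA mice 8 rose and 1 fell (8 and 1 adjusted over the list alone), with adjusted p = 0.0429, or 0.996. In all, 3384 genes rose and 4876 fell in naive mice, and 3408 rose and 4818 fell in OVA mice, beside beta-actin differences of -1.04 and -1.18. With the beta-actin covariate the counts were 3643 and 3178.

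**Figure D3:**
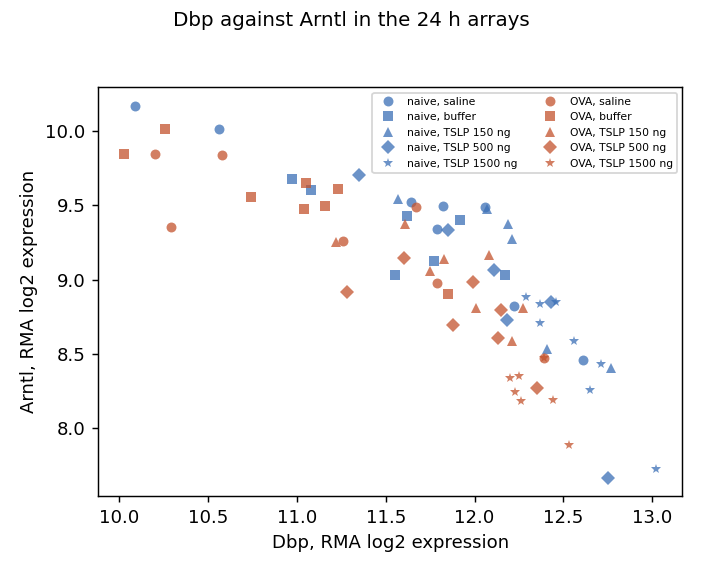
Expression of the clock genes Dbp (x axis) and Arntl (y axis), both RMA log2, in the 72 arrays taken at 24 h, with colour for sensitization and shape for challenge. Arrays with high Dbp have low Arntl, and the 1500 ng arrays lie at the high-Dbp end, with group means of 12.55 in naive and 12.33 in OVA mice against 11.59 and 10.92 with buffer.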

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

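The tests of RNA quality, of outside tissue, of the clock and of the place of arrays between naive and OVA mice were chosen only after the result was seen; the tests by other splits of the samples were chosen before the data were examined.

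In 22 of 180 sets of values, 1 array lay far from the rest of its group, where chance gives about 1 in 20; none of the 22 was an array with gullet keratins. Given are its log2 value and the mean of the others. For the beta-actin 3' minus 5' difference these were naive saline 24 h replicate 3 (1.914 against 1.298), OVA saline 24 h replicate 5 (1.637 against 1.209) and OVA TSLP 150 ng 24 h replicate 3 (1.942 against 1.312). For Mcpt8 it was OVA buffer 24 h replicate 2 (7.123 against 8.181). For Clca1 these were naive saline 6 h replicate 2 (7.803 against 5.196), OVA buffer 6 h replicate 3 (11.56 against 13.86) and OVA TSLP 500 ng 6 h replicate 3 (10.82 against 13.73). Also far off in Clca1 were naive saline 24 h replicate 3 (11.18 against 5.609), OVA TSLP 500 ng 24 h replicate 4 (13.52 against 13.89) and OVA TSLP 1500 ng 24 h replicate 1 (13.19 against 13.91). For Ccl11 these were naive saline 6 h replicate 2 (9.508 against 7.969), naive TSLP 1500 ng 6 h replicate 1 (10.04 against 8.634) and OVA TSLP 1500 ng 24 h replicate 1 (9.798 against 11.9). For Aldh1a3 these were naive saline 6 h replicate 2 (8.002 against 6.034), OVA TSLP 500 ng 6 h replicate 5 (7.871 against 9.673) and OVA TSLP 1500 ng 24 h replicate 1 (5.545 against 9.103). For Prg2 it was OVA TSLP 500 ng 6 h replicate 4 (8.198 against 6.106). For Retnlb these were naive TSLP 500 ng 6 h replicate 8 (8.583 against 5.71) and OVA TSLP 1500 ng 24 h replicate 1 (6.713 against 11.14). For Adipoq these were naive saline 6 h replicate 1 (4.158 against 8.922), OVA TSLP 150 ng 6 h replicate 4 (10.12 against 7.624) and naive TSLP 150 ng 24 h replicate 7 (8.232 against 10.46). Replicate 1 of OVA 1500 ng at 24 h was low in 4 of the genes tested, and naive saline 6 h replicate 2 was high in 3. Naive 500 ng 6 h replicate 8, far off by this test in Retnlb, also had Clca1 at 13.15 (highest of the others 8.81), Il13 at 8.50 (6.32), Ccl11 at 10.84 (10.05) and Adipoq at 3.69 (lowest of the others 7.54). Over 64 genes set apart by sensitization it lay 89.2% of the way from naive to OVA buffer, against 26.6% or less in the other naive arrays. The lowest OVA arrays were OVA buffer 6 h replicate 3 (27.1%) and OVA 500 ng 6 h replicate 3 (31.5%). These values go against the label of replicate 8, which was kept; no explanation was tested.

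A test of the difference itself set apart the effect of 1500 ng TSLP between groups. OVA minus naive mice gave 4291 genes at 6 h and 596 at 24 h, and 24 h minus 6 h gave 2306 in naive and 8117 in OVA mice. For OVA minus naive at 6 h the genes with the largest positive values were Aldh1a3 (3.02), Cxcl9 (2.33), an Igkv15 family segment (2.20), an Igkv14 family segment (2.15) and Cxcl11 (2.03), and with the largest negative values Tert (-1.41), Sema4f (-1.41), Depp1 (-1.35) and Acr (-1.32). At 24 h they were Lemd1 (2.04), Mug1 (1.97), Capn9 (1.94), Egln3 (1.56) and Guca2a (1.53), against Adipoq (-4.19), Tmem45b (-3.73), Car3 (-3.47) and Clca1 (-3.07); the Clca1 value has a limit, since all OVA group means of Clca1 lay from 13.37 to 13.88. For 24 h minus 6 h in naive mice they were Fcna (1.68), Thrsp (1.21), Akr1c18 (1.21), Ephx2 (1.08) and Erich6 (1.06), against Zbtb16 (-1.61), Elf4 (-1.36), Rbbp4 (-1.26) and Zfp40 (-1.24). In OVA mice they were Tert (2.67), Lemd1 (2.36), Erich6 (2.13), Rasgrf1 (2.10) and Dbp (2.10), against Adipoq (-4.85), Car3 (-4.11), Tmem45b (-3.66) and Scara5 (-2.95).

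The first pattern weighed is the 8194 genes called with 1500 ng TSLP in OVA mice at 6 h. A technical explanation is a difference in RNA quality or labelling between the groups, since beta-actin 3' minus 5' differed by -1.31 (SE 0.10): with it as a covariate 1042 genes were called, the median change of the 8194 genes along their own direction went from 0.362 to 0.123 and its SE from 0.0776 to 0.0966, so most calls ended because the change itself shrank. For the 30 members of the type 2, eosinophil chemokine, neutrophil chemokine and interferon lists that rose, the median went from 0.847 to 0.596 and 10 were still called. For these, RNA quality and a response to TSLP cannot be told apart, because the covariate follows the groups. Whether TSLP itself set the beta-actin value also stays open: at 6 h it fell with dose in OVA mice, with means of 2.575, 2.285, 1.793 and 1.26 from buffer to 1500 ng and a slope of -1.02 (SE 0.0776), while the naive slope was -0.0438 (SE 0.144).

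The next pattern is the 6 arrays with keratins 4 and 13 far above the others. Krt4 was at 11.54 or more in them and at 7.60 or less in the others. Tissue from outside the lung may have entered these samples: the mouse gullet has a coat of skeletal muscle, and the muscle genes Acta1 and Ckm were high in 6 of 6 of them and in 2 other arrays. A response to the challenge is argued against by the highest share of a group's arrays, 33.3%, in a buffer group.

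The last pattern is the change of clock genes with 1500 ng TSLP at 24 h. Over the 72 arrays at 24 h, deviations of Dbp and Arntl from their group means had Pearson r -0.802 and Spearman rho -0.802 (permutation p = 1e-05 for both, the smallest that 100000 permutations can give), and r -0.774 without the 2 arrays farthest out. A difference in time of day at collection and a response to TSLP cannot be told apart, because the labels give no clock time: Dbp changed by 0.967 and 1.41 with TSLP, beside SDs of 0.85 and 0.835 in the saline groups. A dose response to TSLP also stays open, since 1 clock gene, Per1, had a called slope the same way in both kinds of mice, out of 1 called in naive and 6 in OVA mice of 14. Clock phase differing between groups as the source of all calls in OVA mice at 24 h is argued against, since 4829 genes were called with the clock score as a covariate and 5359 without it, both without the gullet arrays.

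For each of 34 results 100 splits of the same samples were counted, the real split among them. For 27 results fewer than 5 splits were as large, a bound not adjusted over the 34 results. Values are given as the real result and the highest other split; a dose stands for TSLP against buffer, slope for the dose slope, and OVA minus naive or 24 h minus 6 h for the difference of the 1500 ng effects. Only the real split, 1 of 100, was as large for 500 ng, naive 6 h (5675 and 3686), 500 ng, OVA 6 h (5529 and 3608), 1500 ng, OVA 6 h (8194 and 7204) and 150 ng, naive 24 h (29 and 4). So it was for 1500 ng, naive 24 h (132 and 2), 150 ng, OVA 24 h (1412 and 1344), 500 ng, OVA 24 h (1589 and 470) and 1500 ng, OVA 24 h (5191 and 2782). So it was for OVA against naive buffer, 6 h (4536 and 2455), OVA against naive buffer, 24 h (1156 and 307), OVA minus naive, 6 h (4291 and 2114) and 24 h minus 6 h, OVA (8117 and 2789). So it was for slope, naive 6 h (23 and 3), slope, OVA 6 h (6801 and 5074), slope, OVA 24 h (2029 and 166) and 24 h against 6 h in naive saline (8260 and 6908). So it was for 24 h against 6 h in OVA saline (8226 and 7116), genes shared between naive and OVA mice at 6 h (1508 and 49) and genes shared between naive and OVA mice at 24 h (96 and 0). Splits as large numbered 2 of 100 for 150 ng, naive 6 h (3674 and 5040), buffer against saline, naive 6 h (2014 and 2309) and slope, naive 24 h (61 and 384). They numbered 3 of 100 for 1500 ng, naive 6 h (2071 and 3581), buffer against saline, naive 24 h (1 and 2), OVA minus naive, 24 h (596 and 2459) and 24 h minus 6 h, naive (2306 and 3861). They numbered 4 of 100 for buffer against saline, OVA 24 h (119 and 782). Several splits call many genes, some more than the real split, for reasons not tested. For buffer against saline and the naive 6 h slope the exclusion holds only for the fit over all groups, since a fit on the compared groups alone ended these calls.

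Chance could not be excluded by this split test for 7 results. For genes these were 150 ng, OVA 6 h (16 of 100, 22 and 561), 500 ng, naive 24 h (100 of 100, 0 and 1) and buffer against saline, OVA 6 h (17 of 100, 48 and 840). For lists, tested with 1500 ng, they were naive 6 h (50 of 100, 4 and 12), OVA 6 h (67 of 100, 7 and 21), naive 24 h (42 of 100, 3 and 12) and OVA 24 h (88 of 100, 5 and 19). Some splits again lay far above the real count, for reasons not tested.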

How the results depend on the processing

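Of the alternatives, the 7 added settings were chosen only after the result was seen. The numbers of genes or lists called that moved by over 1.5 times or went to or from 0 are given by setting, with the result of the report in parentheses, with comparisons named as for the splits; the cause was not tested except where it lies in the setting, such as fewer genes or arrays. Counts of genes are from limma, and counts of lists are from camera unless fry is named; beside a count of 0 stands the count at an unadjusted p under 0.05.

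Without the gullet arrays the counts were 3483 for 1500 ng, naive 6 h (2071), 78 for 1500 ng, naive 24 h (132), 1236 for buffer against saline, naive 6 h (2014) and 0 for buffer against saline, naive 24 h (1, and 401 unadjusted). 2745 genes were called for OVA minus naive, 6 h (4291), 94 for slope, naive 24 h (61), 1 list for 1500 ng, naive 6 h (4) and 4 lists for 1500 ng, OVA 6 h (7). 5 lists were called for 1500 ng, naive 24 h (3), 2546 shared by naive and OVA mice, 6 h (1508) and 56 shared by naive and OVA mice, 24 h (96).

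With the beta-actin covariate the counts were 1639 for 150 ng, naive 6 h (3674), 2077 for 500 ng, naive 6 h (5675), 629 for 1500 ng, naive 6 h (2071) and 14 for 150 ng, OVA 6 h (22). 1078 genes were called for 500 ng, OVA 6 h (5529), 1042 for 1500 ng, OVA 6 h (8194), 54 for 150 ng, naive 24 h (29) and 44 for 1500 ng, naive 24 h (132). 1200 genes were called for buffer against saline, naive 6 h (2014), 268 for buffer against saline, OVA 6 h (48), 196 for buffer against saline, OVA 24 h (119) and 967 for OVA minus naive, 6 h (4291). 170 genes were called for 24 h minus 6 h, naive (2306), 3155 for 24 h minus 6 h, OVA (8117), 44 for slope, naive 6 h (23) and 957 for slope, OVA 6 h (6801). 40 genes were called for slope, naive 24 h (61), 3643 for 24 h against 6 h in naive saline (8260), 3178 for 24 h against 6 h in OVA saline (8226) and 1 list for 1500 ng, naive 6 h (4). 14 lists were called for 1500 ng, OVA 6 h (7), 7 lists for 1500 ng, naive 24 h (3), 43 shared by naive and OVA mice, 6 h (1508) and 31 shared by naive and OVA mice, 24 h (96).

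With the beta-actin covariate and without the gullet arrays the counts were 3528 for 500 ng, naive 6 h (5675), 13 for 150 ng, OVA 6 h (22), 1037 for 500 ng, OVA 6 h (5529) and 1446 for 1500 ng, OVA 6 h (8194). 47 genes were called for 150 ng, naive 24 h (29), 24 for 1500 ng, naive 24 h (132), 1069 for buffer against saline, naive 6 h (2014) and 310 for buffer against saline, OVA 6 h (48). 209 genes were called for buffer against saline, OVA 24 h (119), 781 for OVA minus naive, 6 h (4291), 1122 for OVA minus naive, 24 h (596) and 397 for 24 h minus 6 h, naive (2306). 3734 genes were called for 24 h minus 6 h, OVA (8117), 47 for slope, naive 6 h (23), 1588 for slope, OVA 6 h (6801) and 3882 for 24 h against 6 h in naive saline (8260). 3506 genes were called for 24 h against 6 h in OVA saline (8226). Log2 changes that reversed were Elf4 (-0.0479), Myh8 (0.00346) and Tnnc2 (0.404) for 1500 ng, naive 6 h.

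With the clock score and without the gullet arrays the counts were 3644 for 1500 ng, naive 6 h (2071), 121 for 150 ng, naive 24 h (29), 2370 for 150 ng, OVA 24 h (1412) and 1239 for buffer against saline, naive 6 h (2014). 24 genes were called for buffer against saline, OVA 6 h (48), 0 for buffer against saline, naive 24 h (1, and 380 unadjusted), 445 for buffer against saline, OVA 24 h (119) and 415 for OVA against naive buffer, 24 h (1156). 2352 genes were called for OVA minus naive, 6 h (4291), 7 for slope, naive 6 h (23) and 23 for slope, naive 24 h (61). Log2 changes that reversed were TSLP 1500 ng vs buffer, naive 24 h: Arntl (0.00771), TSLP 1500 ng vs buffer, naive 24 h: Dbp (-0.0129), TSLP 1500 ng vs buffer, naive 24 h: Sphk2 (-0.0601), 24 h vs 6 h, naive saline: Dbp (0.279), 24 h vs 6 h, naive saline: Sphk2 (0.221) and 24 h vs 6 h, OVA saline: Sphk2 (0.0268).

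With both covariates and without the gullet arrays the counts were 3471 for 500 ng, naive 6 h (5675), 13 for 150 ng, OVA 6 h (22), 1154 for 500 ng, OVA 6 h (5529) and 1399 for 1500 ng, OVA 6 h (8194). 167 genes were called for 150 ng, naive 24 h (29), 52 for 1500 ng, naive 24 h (132), 2629 for 150 ng, OVA 24 h (1412) and 2671 for 500 ng, OVA 24 h (1589). 1067 genes were called for buffer against saline, naive 6 h (2014), 306 for buffer against saline, OVA 6 h (48), 562 for buffer against saline, OVA 24 h (119) and 481 for OVA against naive buffer, 24 h (1156). 683 genes were called for OVA minus naive, 6 h (4291), 1342 for OVA minus naive, 24 h (596), 390 for 24 h minus 6 h, naive (2306) and 3177 for 24 h minus 6 h, OVA (8117). 1500 genes were called for slope, OVA 6 h (6801), 13 for slope, naive 24 h (61), 2398 for 24 h against 6 h in naive saline (8260) and 1008 for 24 h against 6 h in OVA saline (8226). Log2 changes that reversed were TSLP 1500 ng vs buffer, naive 6 h: Elf4 (-0.0205), TSLP 1500 ng vs buffer, naive 6 h: Tnnc2 (0.432), TSLP 1500 ng vs buffer, OVA 6 h: H2-Aa (-0.0125), TSLP 1500 ng vs buffer, OVA 6 h: Tslp (0.0217), TSLP 1500 ng vs buffer, naive 24 h: Arntl (0.0192), TSLP 1500 ng vs buffer, naive 24 h: Dbp (-0.0535), TSLP 1500 ng vs buffer, naive 24 h: Sphk2 (-0.0801), TSLP 1500 ng effect, 24 h minus 6 h, naive: Elf4 (0.0846), 24 h vs 6 h, naive saline: Dbp (0.419), 24 h vs 6 h, naive saline: Sphk2 (0.290), 24 h vs 6 h, OVA saline: Dbp (0.150) and 24 h vs 6 h, OVA saline: Sphk2 (0.107). For Dbp and Arntl, which are part of the clock score, this is again built into the setting.

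With saline as the reference the counts were 6801 for 150 ng, naive 6 h (3674), 5774 for 1500 ng, naive 6 h (2071), 316 for 150 ng, OVA 6 h (22) and 11 for 150 ng, naive 24 h (29). 2 genes were called for 500 ng, naive 24 h (0), 2 for 150 ng, OVA 24 h (1412), 42 for 500 ng, OVA 24 h (1589) and 4094 for OVA against naive buffer, 24 h (1156). The log2 change of Krtdap (0.146) reversed for 1500 ng, naive 6 h. Those of Ccl11 (-0.0535), Il7r (-0.483), Pdpn (0.0135) and Prg2 (-1.04) did for 1500 ng, OVA 24 h.

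With saline as the reference of the differences the counts were 983 for OVA minus naive, 6 h (4291), 116 for OVA minus naive, 24 h (596) and 4754 for 24 h minus 6 h, naive (2306). Log2 changes that reversed were Ptgs2 (-0.155) for OVA minus naive, 6 h and Gata3 (-0.0259) for OVA minus naive, 24 h.

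With array weights the counts were 5892 for 150 ng, naive 6 h (3674), 3893 for 1500 ng, naive 6 h (2071), 42 for 150 ng, OVA 6 h (22) and 363 for 150 ng, naive 24 h (29). 3 genes were called for 500 ng, naive 24 h (0), 268 for 1500 ng, naive 24 h (132), 3797 for 150 ng, OVA 24 h (1412) and 365 for buffer against saline, naive 6 h (2014). 2 genes were called for buffer against saline, OVA 6 h (48), 2303 for buffer against saline, OVA 24 h (119), 2328 for OVA against naive buffer, 24 h (1156) and 3385 for OVA minus naive, 24 h (596). 3707 genes were called for 24 h minus 6 h, naive (2306), 379 for slope, naive 6 h (23) and 445 for slope, naive 24 h (61).

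With a fit on the compared groups alone the counts were 1177 for 150 ng, naive 6 h (3674), 20 for 1500 ng, naive 6 h (2071), 0 for 150 ng, OVA 6 h (22, and 1077 unadjusted) and 104 for 150 ng, naive 24 h (29). 60 genes were called for 1500 ng, naive 24 h (132), 16 for 150 ng, OVA 24 h (1412), 358 for 500 ng, OVA 24 h (1589) and 0 for buffer against saline, naive 6 h (2014, and 2268 unadjusted). 0 genes were called for buffer against saline, OVA 6 h (48, and 1305 unadjusted), 0 for buffer against saline, naive 24 h (1, and 584 unadjusted), 0 for buffer against saline, OVA 24 h (119, and 1784 unadjusted) and 2338 for OVA against naive buffer, 6 h (4536). 1111 genes were called for 24 h minus 6 h, naive (2306), 0 for slope, naive 6 h (23, and 2040 unadjusted) and 19 for slope, naive 24 h (61).

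With dim genes left out the counts were 11 for 150 ng, OVA 6 h (22), 848 for 150 ng, OVA 24 h (1412), 0 for buffer against saline, naive 24 h (1, and 228 unadjusted) and 51 for buffer against saline, OVA 24 h (119). 3016 genes were called for OVA against naive buffer, 6 h (4536) and 98 for slope, naive 24 h (61).

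With every probe set on its own the counts were 70 for 150 ng, naive 24 h (29), 255 for 1500 ng, naive 24 h (132), 195 for buffer against saline, OVA 6 h (48) and 11 for slope, naive 6 h (23).

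With the mean of all probe sets the counts were 8 for slope, naive 6 h (23) and 11 lists for 1500 ng, OVA 6 h (7).

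With an estimated correlation of list members the counts were 0 lists for 1500 ng, naive 6 h (4, and 0 unadjusted), 0 lists for 1500 ng, OVA 6 h (7, and 0 unadjusted), 0 lists for 1500 ng, naive 24 h (3, and 1 unadjusted) and 0 lists for 1500 ng, OVA 24 h (5, and 0 unadjusted).

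With fry the counts were 0 lists for 1500 ng, naive 6 h (4, and 6 unadjusted), 20 lists for 1500 ng, OVA 6 h (7) and 15 lists for 1500 ng, OVA 24 h (5).

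At a threshold of 0.01 the counts were 535 shared by naive and OVA mice, 6 h (1508) and 27 shared by naive and OVA mice, 24 h (96).

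With the animal number as a replicate block, the count of buffer against saline in naive mice at 24 h was 2 in place of 1. The animal numbers do not pair arrays between groups: deviations of arrays with the same number had a mean r of 0.00275, and of others 0.00339.

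Leaving out each array in turn gave 807 to 3413 genes for 1500 ng in naive mice at 6 h, 7921 to 8196 in OVA mice at 6 h, 54 to 219 in naive mice at 24 h and 4582 to 5528 in OVA mice at 24 h. At 6 h in naive mice the arrays that moved the count by over 1.5 times were naive buffer replicates 6, 2 and 5. At 24 h in naive mice they were naive buffer replicates 8, 7 and 5 and naive 1500 ng replicates 1, 4, 5 and 7. Without naive 500 ng 6 h replicate 8 the 500 ng count was 5670 in place of 5675 and the naive 6 h dose slope was called for 24 genes in place of 23.

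Of the 641 values of named genes, 632 kept their direction and side of the threshold with quantile normalization, 640 with a trended robust prior, 630 with the block, 608 with the mean of probe sets, 593 without the gullet arrays, 520 with the beta-actin covariate, 517 with array weights, 515 with the clock score, 503 with a fit on the compared groups alone, 494 with the beta-actin covariate without the gullet arrays and 424 with both covariates. Of the 310 values that could be set against saline, 220 did, while 60 lost a call, 25 gained one and 5 turned direction. Of the 107 with saline as the reference of the differences, 56 did, while 49 lost a call and 2 turned direction.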

Other observations

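The tests of Cyp11a1, of Mcpt8 by dose and of the slope on beta-actin were chosen only after the result was seen. In OVA mice at 6 h with 150 ng, immediate early genes rose for 2 of 11 (8 adjusted over the list alone), with adjusted p = 1.43e-13, or 0.00477 with an estimated correlation. This comparison called 22 genes, a count that 16 of 100 splits reached, and 0 by limma in a fit on the compared groups alone, with 1077 at an unadjusted p under 0.05. In OVA mice at 24 h with 150 ng, T cell markers rose for 8 of 15 (13 adjusted over the list alone), with adjusted p = 5.72e-07, or 0.356 with an estimated correlation. Against saline 0 of the 15 were called by limma, and T cell markers were lower for 7 of 15 in OVA buffer against OVA saline mice. The 1412 genes of this comparison numbered 2 against saline and 16 in a fit on the compared groups alone. With 500 ng at 24 h in OVA mice, type 2 cytokines and receptors rose for 6 of 10 (7 rose and 1 fell adjusted over the list alone), with adjusted p = 5.54e-05, or 0.221 with an estimated correlation, and 0 of the 10 were called by limma against saline. Along dose in OVA mice at 24 h, NK and cytotoxic cell markers had a negative slope for 6 of 10 (9 adjusted over the list alone), with adjusted p = 0.000195, or 0.865 with an estimated correlation.

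Cyp11a1 was singled out after its values were seen, because mast cells and type 2 lymphocytes can express this steroid enzyme. Its mean in OVA mice at 6 h was 7.12 (SD 0.42, n = 8) with buffer, 7.76 (SD 0.20, n = 7) with 150 ng, 8.32 (SD 0.36, n = 8) with 500 ng and 8.06 (SD 0.41, n = 8) with 1500 ng. In naive mice at 24 h it was 6.84 (SD 0.10, n = 7) with buffer, 6.96 (SD 0.23, n = 6) with 150 ng, 7.50 (SD 0.37, n = 6) with 500 ng and 7.66 (SD 0.26, n = 8) with 1500 ng. Mcpt8 in OVA mice at 6 h had means of 8.10 (SD 0.32, n = 8), 8.88 (SD 0.26, n = 7), 9.74 (SD 0.27, n = 8) and 10.01 (SD 0.58, n = 8) at these doses. Across genes, the change with 1500 ng in OVA mice at 6 h followed the slope of each gene on beta-actin within groups (Pearson r -0.812 over 13494 genes), and 7399 genes followed beta-actin within groups.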
